A study of Drosophila melanogaster with 4 samples.

How the data were processed

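Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos collected over 0 to 24 h of development. The antibody was a rabbit polyclonal serum against fly ORC2, a subunit of the origin recognition complex (ORC), the protein complex that marks potential starts of DNA replication. The labels describe 4 samples: 2 ORC2 ChIP samples, each from its own numbered extraction, and 2 input DNA samples, which are sheared chromatin without immunoprecipitation. No file of the input samples was analysed here, so no background was measured on its own. Per the labels' protocols, chromatin was cross-linked, libraries were size-selected at 150 to 200 bp, and single-end sequencing was done on an Illumina Genome Analyzer II. The design text gives reads of 36 nt.

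The files analysed here were 3 peak lists, one for each ChIP sample and one for the whole series. Per the file headers, coordinates are on the FlyBase release 5.1 genome, and each line names PeakSeq, a peak caller that sets ChIP reads against a control, as its origin. The aligner, the version and thresholds of PeakSeq and the control it used are not given in the sources used here. Each line holds the first and last base of a peak and a score, which the authors deposited with no unit. Tests on the score therefore compare peaks within one list. Means and SDs of a region over both replicates, and the ranking of regions by their mean, set scores of different lists side by side and only describe them. The exception is the upper part of the series-level list by score, the regions scoring above its median. It is cut on this mean and was tested, so tests on it carry the same limit. Peaks were called per sample. Each region of the series-level list was compared with the replicate lists: its ends were the outer ends of overlapping replicate peaks and its score was their mean, with a tolerance of 1e-05, in 540 of 540 regions. The series-level list is thus the set of overlapping replicate peaks, not a separate call on pooled reads, and its presence in both replicates holds by construction. The files hold no read counts, so the sequencing depth is unknown and no value here can be weighed by it.

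Replicate lists were compared by overlap of at least 1 bp. The value expected by chance came from 10000 circular rotations of peak positions within each chromosome arm or scaffold, and p-values from rotations are one-sided, with 0.0001 the smallest they can give. Arm lengths of release 5.1 were not used here. In their place stood the span from the first to the last peak of any list. Scores and widths of matched and unmatched peaks were compared by a two-sided permutation test on the difference of medians with 100000 resamples, whose smallest p is 1e-05. Peak density on X against the 4 large autosomal arms was compared by a two-sided exact binomial test with the spans as expectation. The spacing of series-level peaks was compared with 10000 uniform placements within the 6 arms 2L, 2R, 3L, 3R, 4 and X. Shares of peaks carry Wilson 95% confidence intervals and densities exact Poisson 95% intervals. Both cover counting error only and treat peaks as independent, which clustered peaks are not. The exact binomial tests and Fisher's exact tests treat peaks as independent too. So do the permutation tests on medians and those comparing arms. The p-values of all of these are lower limits. The labels number the extractions but do not say whether they came from separate embryo collections, so the spread between the 2 ChIP samples may be technical.

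Regions named by rule were the 10 highest-scoring regions of the series-level list and the highest-scoring region on each arm or scaffold; any others were chosen after their values were seen, and this is stated. The main tests and most of their alternatives were fixed before the data were examined. The alternatives were a minimum overlap of 50%, a tolerance of 1 kb, the upper part of each list by score, uniform placement in place of rotation, other distances and each replicate's list alone. Added after seeing the data were the merging of peaks within 1 kb, the count of peaks in 100 kb windows with a grid moved by 50 kb, a limit on width, and the comparison of density over the 5 large arms. Most tests under the additional observations were also added later, as stated there. Of the planned tests, 3 (transcription start sites, GC content and 18 fixed gene lists) need the sequence or annotation of release 5.1. The gene table used for names describes Release 6, positions were not converted between releases, and these tests were not run. Genes at the peaks are therefore not named.

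The scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data first. With peaks of the real numbers and widths placed at random, 0 of 20 simulated pairs of replicate lists and 1 of 20 simulated series-level lists reached p = 0.05 in the permutation tests, and 200 of 200 planted shared peaks were recovered. The planted peaks were exact copies, so their recovery checks only the overlap code. The simulated peaks were placed uniformly, with fewer rotations or draws than the analysis. They do not show how the tests behave on clustered peaks. The fast overlap and a plain pairwise overlap differed for 0 of the 1386 peaks of replicate 1.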

Results

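ORC2 binding was mapped in embryos of 0 to 24 h in 2 ChIP-seq samples. ORC is loaded onto DNA before replication and marks the sites where replication can start. Replicate 1 held 1386 peaks covering 242 kb and replicate 2 held 1600 peaks covering 197 kb. The series-level list held 540 regions covering 151 kb, each the union of overlapping peaks of both replicates. Of these regions, 533 lay on the 6 arms 2L, 2R, 3L, 3R, 4 and X, 4 on heterochromatic scaffolds, which are sequence from the gene-poor parts around the centromeres, and 3 on U, the collection of sequence with no assigned chromosome. Peaks were short. The median width was 138 bp in replicate 1, 92 bp in replicate 2 and 243 bp in the series-level list. The number of reads behind a peak is not known, and widths below the sequencing read of 36 nt occurred in 132 peaks of replicate 1 and 303 of replicate 2, but in 1 series-level region.

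**Figure D1:**
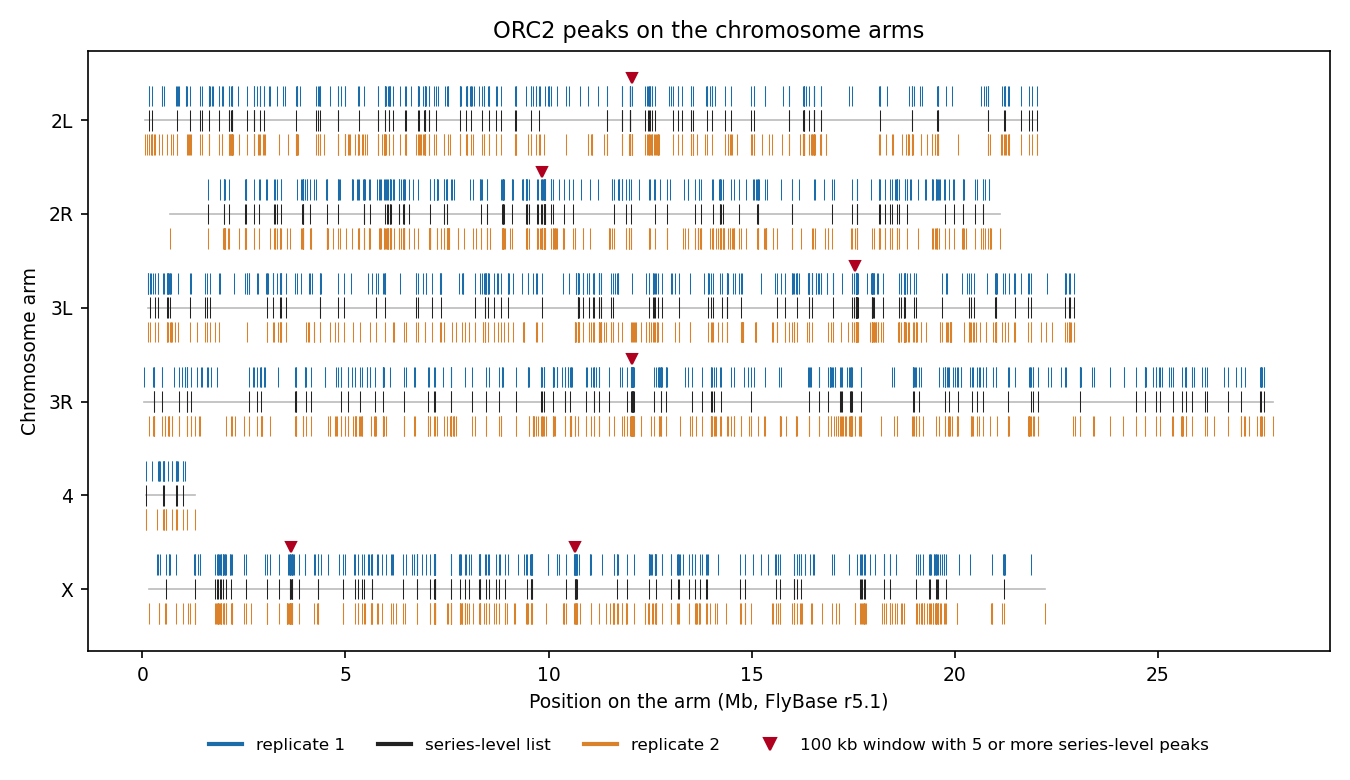
Positions of ORC2 peaks along the 6 chromosome arms in Mb on FlyBase release 5.1, one tick per peak, with replicate 1 above, the series-level list in the middle and replicate 2 below each grey line, which runs from the first to the last peak of any list. Triangles mark the 6 windows of 100 kb that held 5 or more series-level regions; the widest gap between neighbouring series-level regions was 1686 kb.

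The first comparison asked how far the 2 ChIP samples found the same binding sites. Of the replicate 1 peaks, 540 of 1386 (39.0%, Wilson 95% interval 36.4 to 41.6) shared at least 1 bp with a replicate 2 peak. In the other direction 546 of 1600 replicate 2 peaks (34.1%, interval 31.8 to 36.5) met a replicate 1 peak. Rotating the peaks along each arm gave a mean of 0.383% for replicate 1, so the observed overlap was 102-fold above rotation (rotation permutation test, one-sided p = 0.0001, the smallest possible). With no input analysed, the fold cannot tell shared ORC2 binding from background that both samples share. By the rule of 1 bp most peaks of either list were seen in 1 replicate alone. With a tolerance of 1 kb, however, 711 of the 1386 replicate 1 peaks (51.3%, interval 48.7 to 53.9) had a partner. The overlapping peaks also differed in extent: the median region had 55.6% of its length covered by both replicates, and 0 of the 540 regions had the same ends in both. All but 5 regions joined exactly 1 peak from each replicate.

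Wide peaks were found again far more often than narrow ones. In replicate 1, 11.5% (interval 8.58 to 15.3) of the narrowest 25% of peaks, up to 90 bp, met a replicate 2 peak, against 70.0% (65.0 to 74.6) of the widest 25%, from 231 bp up. In replicate 2 the corresponding shares were 12.5% (9.61 to 16.1) and 61.3% (56.4 to 65.9). Matched peaks had a median width of 216.5 bp in replicate 1, against 112 bp for unmatched ones (permutation test, p = 1e-05, the smallest possible). In replicate 2 these medians were 136 bp and 73.5 bp (permutation p = 1e-05). The score did not rank peaks in the same way. Matched peaks of replicate 1 had a lower median score than unmatched ones, 2.10 against 2.27 (permutation test, two-sided p = 1e-05; the difference was smaller, -0.09, with a minimum overlap of 50%, permutation p = 0.0215), and the share matched fell from 49.9% (44.6 to 55.1) in the lowest-scoring 25% to 28.0% (23.5 to 32.9) in the highest-scoring 25%. In replicate 2 the medians were 2.39 and 2.46, a difference that did not pass the permutation test (p = 0.0766), although it did with a minimum overlap of 50% (p = 0.0135). Across the peaks of replicate 1, score and width were inversely related, with a Spearman rho of -0.48. The rho was -0.11 in replicate 2 and -0.10 in the series-level list. Scores were not compared at equal width, so the lower scores of matched peaks cannot be told apart from their greater width. These are correlations across peaks, which are not independent replicates, and no p is given.

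**Figure D2:**
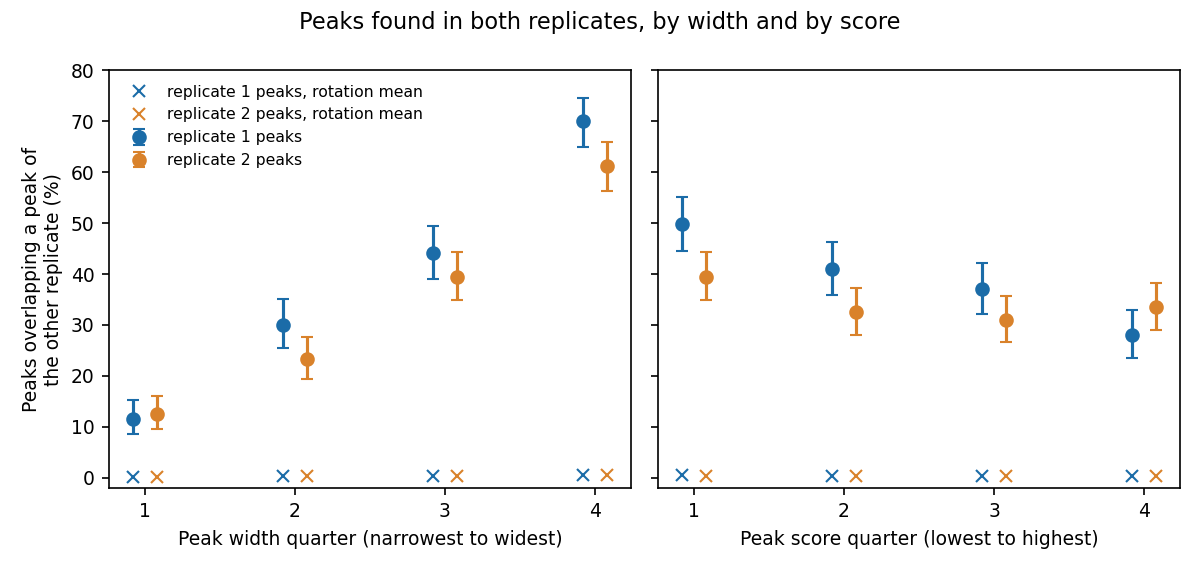
Percent of peaks that overlapped a peak of the other replicate, for 4 equal-sized classes of peak width (left) and of peak score (right). Circles are the observed share with its Wilson 95% interval and crosses the mean of 10000 rotations; the share rose from 11.5% to 70.0% with width in replicate 1 and from 12.5% to 61.3% in replicate 2.

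The shared regions with the highest mean score lay on several arms. Scores were higher overall in replicate 2, with a median of 2.46 against 2.19 in replicate 1, and 8 of the 10 highest regions scored higher there, so the ranking does not weigh both samples alike. The highest-scoring region lay on 2R at 20213031 to 20213241, 211 bp wide, with a mean score of 4.87 ± 0.30 (SD, n = 2). It was followed by a region of 179 bp on 3R at 24948560 to 24948738, with a score of 4.58 ± 0.38 (SD, n = 2). On 2L, the region at 3000755 to 3000882 scored 4.22 ± 0.11 (SD, n = 2), and the scores of its 2 peaks, 4.30 and 4.14, lay closest together among the 10 highest. On 3L, 3 regions were among the 10 highest. The one at 11249401 to 11249536 scored 4.56 ± 3.19, the one at 18665542 to 18665640 scored 4.46 ± 1.96, and the one at 11287609 to 11288334, 726 bp wide, scored 3.98 ± 0.96 (each SD, n = 2). The first of these rests mainly on replicate 2, in which its peak scored 6.82, while the replicate 1 peak scored 2.30, close to that list's median of 2.19. Of the other four, the 2R region at 3950379 to 3950499 rested mainly on replicate 1, with a score of 5.63 there and 2.34 in replicate 2. The remaining regions were at 2193495 to 2193859 on 2L (score 4.21 ± 1.41), at 9580364 to 9580472 on X (4.04 ± 1.61) and at 5465471 to 5465611 on 2R (3.94 ± 0.79). Of these 10 regions, 8 were narrower than the median region of 243 bp.

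On chromosome 4, the small chromosome that is largely heterochromatic, the highest-scoring region was at 529136 to 529290 with a score of 2.57 ± 0.42 (SD, n = 2). It ranked at 154 of the 540 regions. The heterochromatic scaffolds held 1 shared region each on 2LHet, 2RHet, 3LHet and 3RHet. The region on 3LHet at 601531 to 601625 scored 2.998 ± 0.12 and the one on 3RHet at 776762 to 777292 scored 1.90 ± 0.46. The region on 2RHet at 3182322 to 3182902 scored 1.74 ± 0.56 and the one on 2LHet at 190936 to 191765 scored 1.501 ± 0.29 (each SD, n = 2). The last 3 were 531, 581 and 830 bp wide, each wider than 93.3% or more of all regions. The best region on U lay at 8559202 to 8559400 and scored 2.40 ± 0.10. The widest region of the series-level list, named after its value was seen, was also on U, at 4028260 to 4029948, 1689 bp wide, and its score of 1.42 was the lowest of all.

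ORC2 regions were about equally dense on X and on the autosomes. X carried 101 regions over a span of 22.1 Mb, or 4.58 per Mb, and the 4 large autosomal arms carried 426 over 93.0 Mb, also 4.58 per Mb. The ratio of X to autosomes was 1.00 (95% interval 0.796 to 1.24; exact binomial test, two-sided p = 1). It was 1.01 in the list of replicate 1 and 0.982 in that of replicate 2. With no input or depth analysed, these densities of called peaks were not corrected for the lower dosage of X in male embryos. Among the upper part of the series-level list by score, X held 66 regions and the autosomal arms 197, a ratio of 1.41 (interval 1.05 to 1.88, exact binomial p = 0.0185). The test treats regions as independent, which clustered regions are not, so this p is a lower limit. Since X was not denser over the whole list, it held fewer of the lower-scoring regions than its span gives. The ratio of 1.41 thus reflects how scores were distributed and not a greater number of regions on X. Among single arms, the density was 5.101 per Mb on 2L (Poisson interval 4.20 to 6.14), 5.14 on 2R (4.21 to 6.23), 4.69 on 3L (3.84 to 5.67) and 3.67 on 3R (2.99 to 4.45). The spread over the 5 large arms did not pass a permutation test with multinomial draws, chosen after seeing the values (one-sided p = 0.098 in the series-level list, 0.34 in replicate 1 and 0.0604 in replicate 2). Chromosome 4 held 6 regions, 4.99 per Mb, with an interval of 1.83 to 10.9 that excludes none of the other series-level densities. The replicate lists placed chromosome 4 at opposite ends of their densities, but on few peaks, with overlapping intervals, and this was not tested. Replicate 1 had 22 peaks on chromosome 4, or 18.3 per Mb (11.5 to 27.7), its highest density, with an interval above the 10.7 per Mb of 3R and the 11.4 of 2L, and replicate 2 had 14, or 11.6 per Mb (6.37 to 19.5), its lowest.

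**Figure D3:**
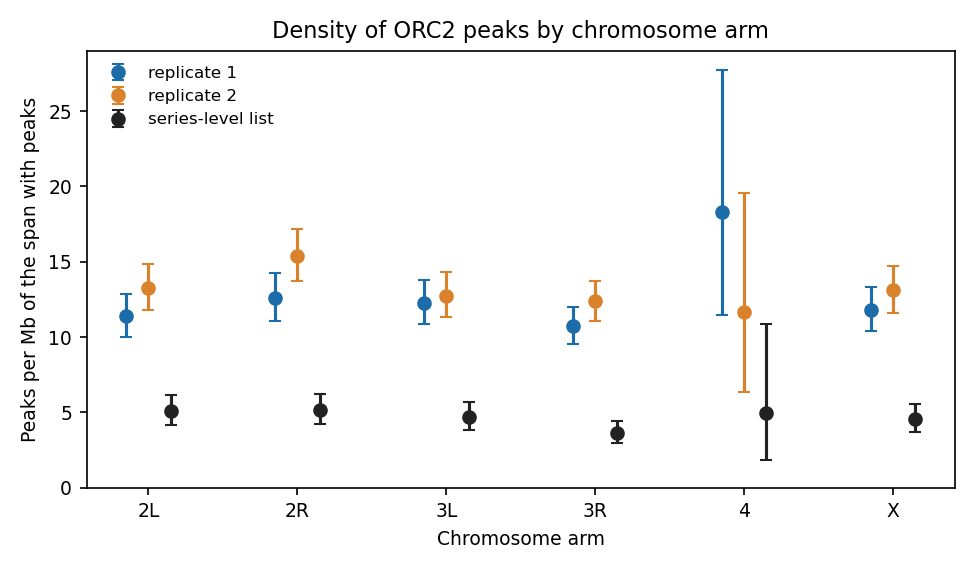
Peaks per Mb of the span with peaks on each chromosome arm, for replicate 1, replicate 2 and the series-level list, with exact Poisson 95% intervals as bars. Series-level densities lie between 3.67 per Mb on 3R and 5.14 per Mb on 2R; the wide intervals of chromosome 4 come from its few peaks.

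ORC2 regions were clustered along the arms. Of the 533 regions on the 6 arms, 180 (33.8%, Wilson 95% interval 29.9 to 37.9) had another region within 10 kb, against a mean of 9.002% when the same regions were placed uniformly, a 3.75-fold excess (placement permutation test, one-sided p = 0.0001, the smallest possible). The share was 27.0% within 5 kb, against 4.73% in uniform placement, and 41.1% within 20 kb, against 17.0%. The median gap between neighbouring regions was 112 kb, with 37 gaps under 1 kb. Joining regions within 1 kb of each other, so that a site split by the caller counts once, left 25.2% of 496 regions with a neighbour within 10 kb, 2.98-fold above uniform placement (placement permutation test, one-sided p = 0.0001). The single replicate lists gave 46.3% in replicate 1 and 54.6% in replicate 2, which were 2.17-fold and 2.32-fold above uniform placement. Uniform placement treats every base of the span as able to hold a peak, and no input was analysed. The excess therefore cannot tell clustered ORC2 binding from uneven background or uneven placement of reads.

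In a fixed grid of 100 kb windows, 6 windows held 5 or more regions, where uniform placement gave a mean of 0.142 and at most 3 such windows (placement permutation test, one-sided p = 0.0001). On 3L, 7 regions lay between 17526611 and 17584137, with scores up to 3.46, and the window held 8 peaks of replicate 1 and 9 of replicate 2. On 3R, 7 regions lay between 12034088 and 12086865, where replicate 1 had 13 peaks and replicate 2 had 15, the highest peak counts of the 6 windows in both samples. On X, 7 regions lay between 3637862 and 3675231, in a window with 8 peaks of replicate 1 and 14 of replicate 2. A second window on X held 5 regions between 10638869 and 10678708, among them the one at 10665818 to 10666016 with a score of 3.92; it had 8 peaks of replicate 1 and 7 of replicate 2, and joining regions within 1 kb left 3. On 2R, 5 regions lay between 9812861 and 9896064, in a window with 7 peaks of replicate 1 and 10 of replicate 2. The most compact group was on 2L, where 6 regions between 12004064 and 12012588 covered 4105 bp of 8.53 kb; joined within 1 kb they made 2 regions, and the window held 9 peaks of replicate 1 and 11 of replicate 2. After such joining, 4 windows still held 5 or more. With the grid moved by 50 kb, 6 windows passed again, but not all the same ones. The windows on 3L, 3R, 2L and 2R each overlapped a passing window, and the one on 3L from 17550001 to 17650000 then held 9 regions. Neither of the 2 windows on X did. In their place stood a window on X from 7150001 to 7250000 and one on 3L from 17950001 to 18050000, each with 5 regions. These windows were looked at after the lists had been seen, and the limit of uniform placement given for the spacing holds for them too.

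**Figure D4:**
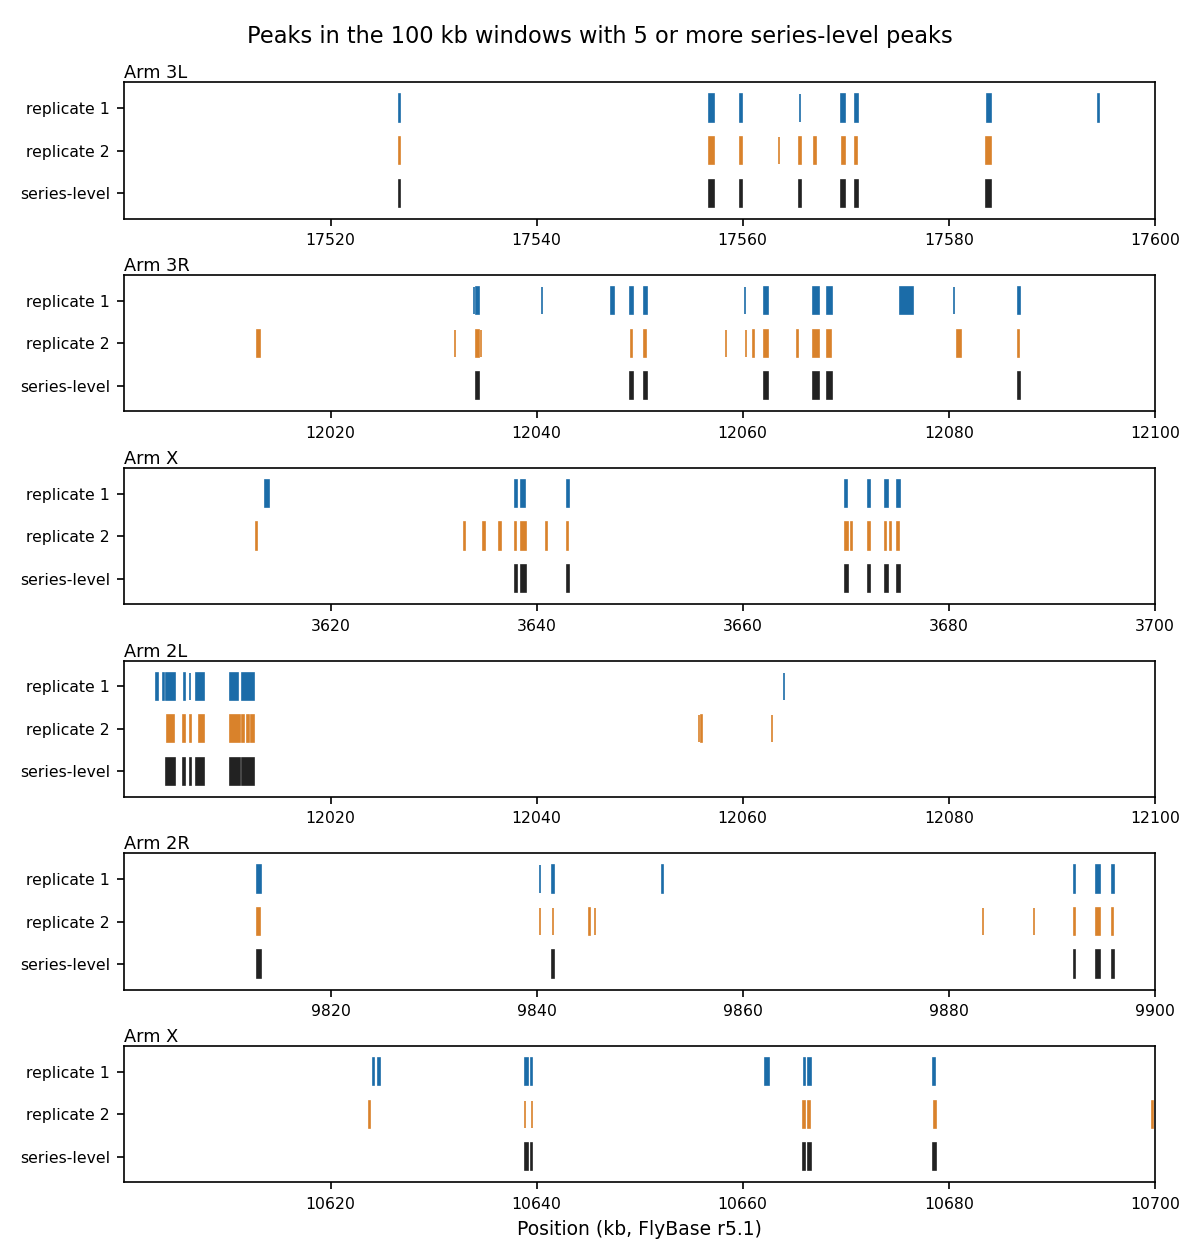
Peaks of replicate 1, replicate 2 and the series-level list in the 6 windows of 100 kb with 5 or more series-level regions, with position in kb on FlyBase release 5.1; each box spans a peak from its first to its last base, drawn with a thin outline so that the narrowest stay visible. The window on 3R holds 13 and 15 replicate peaks and 7 series-level regions, and the 6 regions on 2L lie within 8.53 kb.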

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

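The peaks given first lay on sequence outside the 6 arms, which the density and spacing comparisons left out. All tests in this part were chosen after the result was seen, apart from the comparison of crowding on U with the arms and the test of recurring scores. Those were fixed before their own values were seen, but were not among the tests fixed before the data were examined. The unplaced sequence U held 4 peaks of replicate 1 and 37 of replicate 2, and the heterochromatic scaffolds held 14 peaks of replicate 1 and 20 of replicate 2. No file of input DNA was analysed here, so no background was measured for them.

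On U the samples differed: 0.289% of replicate 1 peaks and 2.31% of replicate 2 peaks lay there, and 3 of the 37 replicate 2 peaks met a peak of replicate 1. A general excess of calls in replicate 2 is argued against by the unequal shares (Fisher's exact test, two-sided p = 6.57e-07, odds ratio 8.18), and narrow calls by the median width, 202 bp on U against 91 bp on the arms (permutation test with 20000 resamples, p = 5e-05, the smallest possible). Along the coordinates of U, replicate 2 peaks were more crowded than in uniform placement. A neighbour within 10 kb was present for 32.4% of them, against 7.14% (permutation test, one-sided p = 0.0007). U collects sequence with no assigned chromosome, so distances and densities along it need not be those on a chromosome. The comparison with the arms, where the share was 54.6%, cannot tell whether a few stretches carry the excess, because the arms hold 13.3 peaks per Mb and U holds 3.72. On these coordinates, a few crowded stretches are argued against as the whole source by a test added later. Joining peaks within 10 kb left 30 loci on U in replicate 2 and 4 in replicate 1 (Fisher's exact test against loci on the arms, two-sided p = 6.68e-06). Different handling of reads that match repeats stays open and was not tested. The design names no biological difference between the 2 ChIP samples, so none was tested.

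Most peaks of one replicate shared no base with a peak of the other, although with a tolerance of 1 kb 51.3% of replicate 1 peaks had a partner. Whether narrow calls account for all of this cannot be told apart from other causes: 70.0% of the widest 25% of replicate 1 peaks were matched, and a wide peak can also be missed by a narrow call in replicate 2, where the median width was 92 bp. They may account for part: the excess over rotation was 58.1 percentage points larger in the widest than in the narrowest 25% of replicate 1, and 48.5 points larger in replicate 2. Peak edges shifted by up to 1 kb are argued against as the whole cause, because 171 of 846 unmatched replicate 1 peaks, 20.2% (Wilson interval 17.6 to 23.1), had a replicate 2 peak within 1 kb, although rotation gave 2.604% (permutation test, one-sided p = 0.0001). Differing read depth stays open, since no depth is known, and a biological difference between the samples was not tested.

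High scores lay on narrow peaks, most clearly in replicate 1. A candidate explanation is that a score is a ratio of small whole numbers of reads in such peaks, which would make exact scores recur. Split at the median width, 51.4% of the narrower and 20.5% of the wider replicate 1 peaks had a score that another peak of the list shared to every printed digit (Fisher's exact test, two-sided p = 9.22e-34). In replicate 2 the shares were 64.8% and 28.9% (Fisher's exact p = 8.09e-48). Recurrence does not show why scores on narrow peaks are high. The most frequent score of replicate 1, 2.154, lay below that list's median of 2.185. That of replicate 2, 2.599, lay above its list's median of 2.455. Scores recurred in 46.9% of replicate 2 peaks against 36.1% in replicate 1, although the relation of score to width was weaker in replicate 2 (Spearman rho -0.11 against -0.48). The explanation stays a hypothesis about how the score was made. The reads that would settle it were not analysed here.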

How the results depend on the processing

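The overlap of the replicates stayed above chance at a permutation p of 0.0001 under every alternative run, from 19.3% for the upper part of each list by score to 51.3% with a tolerance of 1 kb, as did the spacing of regions, from 25.2% to 54.6%. The 19.3% is lowered by the cut of both lists, since partners outside the upper part no longer count. With peak width in place of score, the difference between matched and unmatched peaks had the other sign, 104.5 bp in replicate 1 and 62.5 bp in replicate 2. Width is another quantity than the score and was inversely related to it (Spearman rho -0.48 and -0.11). The other sign is therefore no reversal of the score result. Which of the 2 quantities goes with matching on its own was not tested. With a minimum overlap of 50%, the score difference of replicate 1 shrank from -0.17 to -0.09 (permutation p = 0.0215), and that of replicate 2 went from -0.07, which did not pass, to -0.11, which did; the cause was not tested. The ratio of X to autosomal density, 1.00, rose to 1.41 in the upper part of the list by score. It passed the test there, with a p that is a lower limit. The higher scores on X, given among the other observations, rest partly on the same peaks and are no separate explanation of the ratio. With each replicate list alone the ratio over all peaks was 0.982 and 1.01. Presence of series-level regions in both replicates is 100% by construction, and 63.3% when peaks of each replicate had to cover 50% of the region. The means of the 16 named regions rest on 2 scores each. The planned tests of transcription start sites, GC content and gene lists, with their alternatives, were not run, because they need the sequence or annotation of release 5.1. No file of the input samples was analysed here, so no paired analysis was run. With no read counts, depth sets no limit that could be stated.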

Other observations

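Scores of ORC2 peaks were higher on X than on the 4 large autosomal arms in both replicate lists, while no difference in width passed a test in either replicate. In replicate 1 the median score was 2.30 for 261 peaks on X and 2.15 for 1085 autosomal peaks, a difference of 0.15 (permutation test, two-sided p = 0.00035). In replicate 2 the medians were 2.62 for 289 peaks and 2.42 for 1240 peaks (permutation p = 3e-05). Over these 2 comparisons the adjusted permutation p-values (Benjamini-Hochberg) were 0.00035 and 6e-05. The permutations shuffle single peaks as if independent, which clustered peaks are not, so the p-values on X scores are lower limits. Median widths were 149 and 138 bp in replicate 1 (permutation p = 0.19) and 91 and 92 bp in replicate 2 (p = 0.94). The comparison was chosen after the X ratio of the higher-scoring series-level regions had been seen, and the peaks that make up those regions are in both lists. Without them, in a test also added later, the difference passed in replicate 2, with medians of 2.63 and 2.44 (permutation p = 0.00057), but not in replicate 1, where it was 0.113 (permutation p = 0.0563). The 2 replicate lists share the genome and the method, and whether the difference lies in ORC2 or in the lower dosage of X in male embryos was not tested.

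Over the 5 large arms together, series-level regions were not detectably fewer next to the centromeres, a test fixed before its values were seen. The third of each of the 5 large arms next to the centromere held 164 of 527 series-level regions, 31.1% (Wilson 95% interval 27.3 to 35.2), the middle part 198 and the part farthest from it 165 (exact binomial test of the first, two-sided p = 0.288). That part held 404 peaks of replicate 1, fewer than its length gives (exact binomial p = 0.0101), and 511 of replicate 2 (exact binomial p = 0.957), so the replicate lists do not share the result. Arms went both ways: on X 22 of 101 regions lay in that part (exact binomial p = 0.0148, Benjamini-Hochberg adjusted over 5 arms 0.0739), and on 3L 45 of 107 (p = 0.0645, adjusted 0.161). Single arms passed in the replicate lists. Replicate 1 had fewer peaks than length gives in that part of 2L, 58 of 250 (exact binomial, adjusted p = 0.00297), and of X, 66 of 261 (adjusted p = 0.0143). Replicate 2 had more in that part of 3L, 129 of 291 (exact binomial, adjusted p = 0.00054). The binomial tests treat peaks as independent, so with clustered peaks these p-values are lower limits.

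The share of matched peaks ran from 34.2% on 3R to 44.8% on 2L in replicate 1, a range chosen for a test after it was seen. The difference among the 5 large arms did not pass (permutation test, one-sided p = 0.145). Replicate 2 is no separate test, since a match counts in both lists.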
